A study of Homo sapiens and Mus musculus with 22 samples.

How the data were processed

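RNA was measured by sequencing of poly(A)-selected libraries in U2OS, a human osteosarcoma line, and L929, a mouse fibroblast line. Of the 22 samples of the series, 14 were RNA samples and 8 were chromatin immunoprecipitation samples or their inputs, which were not analysed here. The RNA samples formed 3 sets. The first held mock-treated U2OS cells that were wild type (WT) or came from 2 SETDB1 knockouts (KO1 and KO2), with 2 libraries per group. The second held U2OS cells with a vector or an ATG5 knockdown (KD), mock-treated or treated with BIX-01294 (BIX), with 1 value per group. Per the labels, each of these 4 values stands for 2 replicates, and the separate values were not held here. The third held L929 cells that were cGAS WT or cGAS KO, mock-treated or treated with BIX, with 1 library per group. BIX was given at 10 µM for 12 h. The treatment note of every RNA sample says that all cells received BIX, while the sample names say mock for part of them. The names were followed, so mock means the name here, and what the mock cells received is not given in the sources used here.

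The authors made TruSeq libraries, sequenced them as paired ends on an Illumina HiSeq instrument, checked the reads with FastQC, trimmed them with cutadapt, aligned them with TopHat2 to hg19 or mm10 and quantified genes with Cufflinks. Versions, options, the gene annotation and the strandedness of the libraries are not given in the sources used here. The deposited tables give FPKM per gene, 1 table per set, and these values were used as they stood. The sum of a column ranged from 445281 to 564049.5.

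Of the entries of a symbol listed more than once, the one with the highest mean FPKM was kept, which left 24549 genes in the SETDB1 table, 23760 in the ATG5 table and 23849 in the cGAS table. Loci that join several symbols (525, 1396 and 322) were kept as 1 gene each. Genes of short non-coding RNAs (2004, 1994 and 1243), for which FPKM is unstable, were found by name and left out of the tests and counts. The name patterns missed at least 1 such gene, SNAR-G1. FPKM was used as log2(FPKM + 1).

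Read counts are not given in the sources used here, so depth was compared within a table only. Genes with few reads have FPKM values in steps, and the commonest ratio between 2 libraries among genes under an FPKM of 0.3 gives their relative reads. In L929, between 17.5% and 22.5% of such genes fell in a single window of 1%, against 0.25% to 0.26% for an even spread. The cGAS WT BIX library had 0.738 of the reads of cGAS KO BIX, the cGAS KO mock library 0.997 and the cGAS WT mock library 0.989. In the SETDB1 table the steps lined up between libraries of the same replicate number (17.8% to 22.8%) more than between numbers (6.94% to 8.64%). In replicate 1, KO2 had 0.887 and WT 0.912 of the reads of KO1. In replicate 2 these were 0.723 and 0.784. The pooled U2OS values had no clear steps (1.62% to 3.26%), and no relative depth was taken from them.

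The SETDB1 groups were compared with limma (a linear model per gene, moderated variance with a trend on expression) on genes with FPKM of at least 1 in 2 or more libraries. Contrasts were the mean of KO1 and KO2 against WT, each KO against WT, and KO1 against KO2. P values were adjusted by the Benjamini-Hochberg method over all genes of a contrast and called below 0.05. Gene lists written by hand, 36 in all, were tested with camera when they had at least 5 members, with the preset correlation of 0.01 and again with a correlation estimated from the residuals. As each KO shares the 2 WT libraries, their overlap was set against 20 simulated tables with no KO effect.

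The 8 comparisons between single values (BIX against mock in each of the 4 backgrounds, and KD or KO against its control in mock and in BIX) had no replicates. Genes at FPKM 1 or more in at least 1 of the 2 values were counted when at least 2-fold apart, and no p was computed. The median of each list was placed among 10000 random lists of the same size, matched on expression in 20 bins. The 4 BIX log2 ratios were also tested against 0 with limma, with each background as 1 unit, on genes whose symbols matched between human and mouse when case was ignored and with FPKM of at least 1 in 2 or more of the 8 values.

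Named genes are those with the largest difference in each direction past the test. In the SETDB1 set they also had to pass in the mean, in KO1 and in KO2, in the same direction. Across the 4 backgrounds they also had to have the same sign in 4 of 4. Where untested, they were 2-fold or more apart in the same direction in both genotypes or treatments, with FPKM of at least 5 in 1 of the values. Up to 4 members with the largest difference were taken from each list, and the targets of the study were added. For list members it was enough to pass in the mean of the KOs or across the 4 backgrounds. Where untested, being 2-fold apart in 1 comparison was enough. Not every gene that met these rules is named. Alternatives covered the pseudocount, the filter on low values, scaling, short RNAs, a replicate block, the trend, leaving out each library, fold limits of 1.5 and 3, and the correlation of the list test. The groups, comparisons, lists and these alternatives were set before the data were examined. Leaving out merged loci was added afterwards. Centring of the 4 BIX ratios was first done on the median of all tested genes, which moved nothing, and was then changed to the median of genes with FPKM of at least 5 in both values.

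The tests were tried on simulated data. With the SETDB1 design, 39 of 50 genes made 0.5 apart (log2) were found, all 50 at 1, 2 and -1, and 15 of 204 calls were false. With the 4-background design, 38 of 50 genes made 1 apart were found, and 8 of 195 calls were false. Gene positions came from the GRCh38.p14 annotation. No mouse annotation was held. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.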

Results

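U2OS cells with SETDB1 KO, U2OS cells with ATG5 KD and L929 cells with cGAS KO were compared with their controls, and the last 2 also with and without BIX, an inhibitor of the H3K9 methyltransferases EHMT1 and EHMT2. The first set had 2 libraries per group and was tested. The others had 1 value per group, so their single comparisons had no replicates and are described without a test. Together, 4 contrasts of the SETDB1 set, 8 single comparisons and 1 comparison across the 4 BIX backgrounds were made.

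SETDB1 mRNA was at 9.65 ± 0.464 FPKM (mean ± SD, n = 2) in WT, 6.46 ± 0.797 in KO1 and 7.12 ± 0.321 in KO2. It fell by 0.45 on the log2 scale (SE 0.109, adjusted p = 0.0422) in the mean of the KOs, while neither KO alone passed (adjusted p = 0.0557 and 0.2). In the other 2 sets the targets have single values without a test. ATG5 was at 11.3 FPKM in the vector mock value and 10.1 in the ATG5 KD mock value, and at 12.3 and 13.4 with BIX. Mb21d1, the mouse gene for cGAS, was at 2.82 in cGAS WT mock and 1.19 in cGAS KO mock, and at 3.47 and 4.41 with BIX. The KD and KO are therefore named by their labels. Gene-level FPKM cannot show a small deletion in a KO. For ATG5, the log2 difference of KD from vector was -0.155 in mock and 0.116 with BIX, so its RNA showed no clear knockdown in either.

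SETDB1 is a methyltransferase that silences genes through H3K9me3, and its KO libraries had higher RNA of several genes at low levels in WT. LINC01164 rose by 3.55 on the log2 scale (SE 0.124, adjusted p = 1.26e-08), from 0.761 ± 0.256 FPKM in WT to 21.3 ± 3.11 in KO1 and 18.0 ± 0.796 in KO2 (n = 2 each). ACTL8, a cancer-testis gene, rose by 3.53 (SE 0.158, adjusted p = 9.37e-08), and ZFP30, a zinc finger repressor gene, by 3.20 (SE 0.111, adjusted p = 1.26e-08; 5.65 FPKM in WT, 66.7 in KO1 and 54.7 in KO2). The list of germline and cancer-testis genes, which does not hold ACTL8, did not rise as a whole. Of its 12 tested genes, 1 was called higher and 0 lower, with a median of -0.19 (list test adjusted p = 0.271). ZNF733P was listed at 0 in both WT libraries and at means of 7.47 and 7.11 in the KOs. LINC00664 (2.97), LINC00665 (2.48), AURKC (2.30) and ZNF578 (2.20) followed. Among genes called lower in all 3 contrasts against WT, INSL4 was the lowest in the KOs, with a fall of 1.51 (SE 0.16, adjusted p = 0.000101). HBE1 (-1.41), COL8A1 (-1.32), TNFAIP6 (-1.26), SULT1A1 (-1.2), LOC101929427 (-1.19) and COL11A1 (-1.16) followed.

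**Figure D1:**
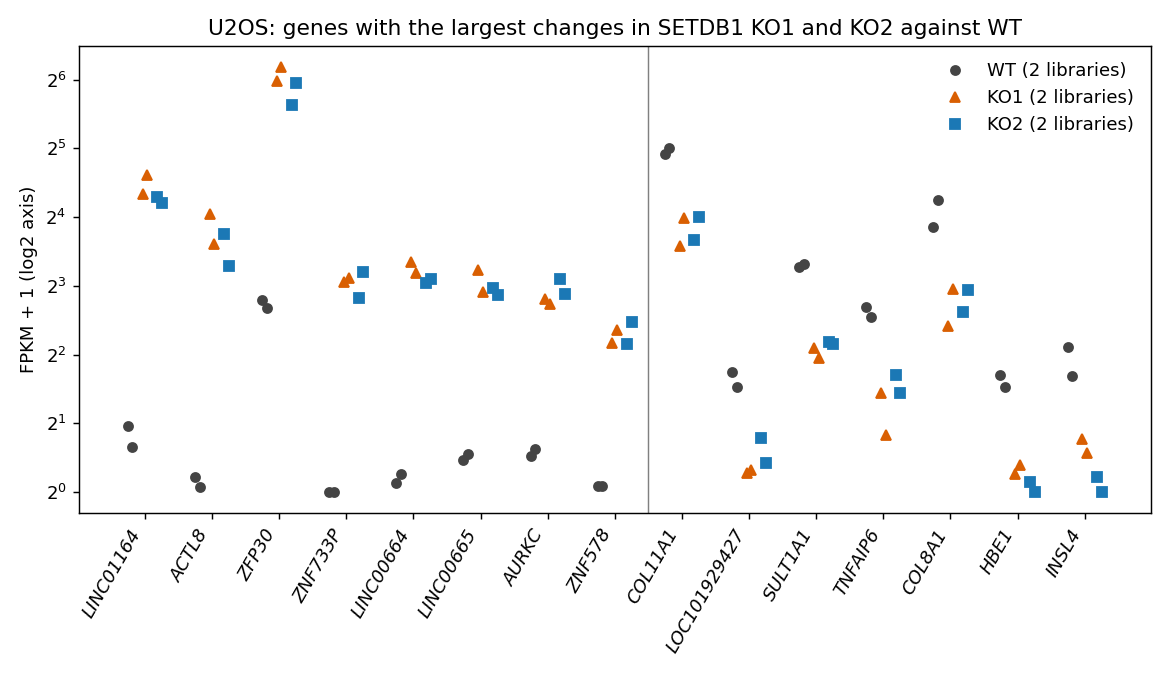
FPKM + 1 (log2 axis) of 15 genes with the largest differences among those called in all 3 SETDB1 KO contrasts against WT. WT, KO1 and KO2 have 2 libraries each. Each point is 1 library.

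By group, zinc finger genes made up 146 of the 311 genes that rose. Of 461 tested, 146 rose and 1 fell (198 and 4 adjusted over the list alone), with a median of 0.25 (list test adjusted p = 1.09e-45, adjusted p = 0.181 with the estimated correlation). Clustered protocadherins, cell adhesion genes arrayed on chromosome 5, rose in 15 of 16 (15 adjusted over the list alone), with a median of 1.26 (adjusted p = 2.11e-36, adjusted p = 0.181 with the estimated correlation). PCDHB2 rose by 2.17, the joined PCDHG locus by 1.67, the joined PCDHA locus by 1.52 and PCDHB8 by 1.42. Replication-dependent histone genes rose in 7 of 29 (13 adjusted over the list alone), with a median of 0.39 (adjusted p = 1.85e-10, adjusted p = 0.15 with the estimated correlation). Among them HIST1H4E rose by 1.01, HIST2H2BE by 0.69 and HIST1H2BD by 0.55. HIST1H4E did not pass in KO1 alone (limma adjusted p = 0.406). HIST1H2BG was listed at 0 in WT and at means of 1.35 and 0.913 in the KOs. The libraries were poly(A)-selected, which favours polyadenylated transcripts, so these values need not follow total histone mRNA. The list named endogenous retrovirus genes had 2 of 6 higher (2 adjusted over the list alone). Its list test gave adjusted p = 0.0106, and adjusted p = 0.401 with the estimated correlation. The joined ERV3-1,ZNF117 locus rose by 1.34 and also counts as a zinc finger gene. PEG10, also on the list of imprinted genes, rose by 0.66 but passed in neither KO alone (limma adjusted p = 0.0704 and 0.0672). Lists past the test on the higher side numbered 4, and 3 with merged loci left out or with FPKM of at least 5.

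Some lists were lower as a whole with no single member past the limma test. Extracellular matrix genes had a median of -0.20 over 24 genes (adjusted p = 4.45e-05, adjusted p = 0.7 with the estimated correlation), with 0 called, 9 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. The collagen genes COL8A1 and COL11A1, which were called lower, are not on this list. Hypoxia and glycolysis genes had a median of -0.19 over 21 (adjusted p = 0.000194, adjusted p = 0.401 with the estimated correlation), with 0 called, 6 lower unadjusted and 3 adjusted over the list alone. Respiratory chain genes were at -0.10 over 82 (adjusted p = 0.00431, adjusted p = 0.828 with the estimated correlation; 0 called, 6 lower and 2 higher unadjusted, 0 adjusted over the list alone) and ribosomal protein genes at -0.09 over 72 (adjusted p = 0.00205, adjusted p = 0.828 with the estimated correlation; 0 called, 5 lower unadjusted, 0 adjusted over the list alone). These 2 lists did not pass in KO2 alone (adjusted p = 0.102 and 0.0992). The lists past the test on the lower side numbered 4, and 2 after quantile normalization or without KO2 replicate 2. Thus 8 of 32 lists passed with the preset correlation and 0 with the estimated one. Correlation between genes cannot be the sole reason for the 0. In the mean of the KOs, the replication-dependent histone list had an estimated correlation of -0.028, below the preset value. Its unadjusted list test p still went from 1.73e-11 with the preset correlation to 0.0047 with the estimated one. With the estimated correlation, camera also takes its degrees of freedom from the residuals, and 2 libraries per group leave few. With the preset correlation it takes them from the number of genes. A list can thus fail the estimated setting for lack of power. How much each difference between the settings contributed was not examined. Interferon-stimulated genes went both ways (of 23, OAS3 rose by 0.63 and IFI27 fell by 1.03). IFI27 did not pass in KO2 alone (limma adjusted p = 0.0573). ATF7IP, which encodes a SETDB1 partner, rose by 1.2 (SE 0.116, adjusted p = 4.88e-05), from 14.3 ± 0.0457 FPKM in WT to 33.0 ± 1.86 in KO1 and 35.6 ± 7.5 in KO2.

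Across 12494 genes, 411 were called in the mean of the KOs (311 higher, 100 lower), 308 in KO1 (242 and 66) and 310 in KO2 (253 and 57). All 3 contrasts called 216 genes higher and 35 lower. KO1 against KO2 gave 0 genes by limma, with 201 at an unadjusted p under 0.05. As the KOs share their WT libraries, their log2 differences correlate even without any effect. The correlation of the 2 sets was 0.876, against 0.498 in simulated tables with no KO effect (genes are not independent replicates). The simulated number of genes called higher in both KOs was 0. With no effect, hardly any gene is called in either KO, so this number was fixed in advance. It cannot show how much of the shared calls comes from the shared WT libraries. The KO2 count was 171 without KO2 replicate 2 and 204 without WT replicate 1. The lower side was less stable than the higher. It held 59, 27 and 27 genes (mean, KO1 and KO2) with no filter on low values and 48, 35 and 23 with FPKM of at least 5. Without WT replicate 2 it held 39 genes in the mean, 24 in KO1 and 27 in KO2. For KO2 it held 18 without KO2 replicate 2, 29 without WT replicate 1 and 86 without KO1 replicate 1 or, in turn, KO1 replicate 2, and for KO1 it held 42 without KO1 replicate 1.

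In U2OS, BIX came with much higher RNA of stress and early response genes in both the vector and the ATG5 KD values. DDIT3, a transcription factor of the integrated stress response, was at 8.45 FPKM in mock and 260.1 with BIX in the vector cells, and at 9.36 and 327 in the KD cells. PPP1R15A, its companion in that response, went from 14.1 to 268 and from 16.5 to 459.5. The chemokine gene CXCL8 stood at 1.11 and 40.0 (KD 1.19 and 68.3), the metallothionein gene MT1X at 44.6 and 1035 (KD 40.8 and 1106), FOS at 3.96 and 62.5 (KD 4.06 and 209.8) and GEM at 3.98 and 76.3 (KD 5.14 and 139.6). On the lower side were FOXS1 (9.44 in mock and 0.605 with BIX in vector), LBH (60.3 and 8.40), FAM120B (14.2 and 1.93), EDN2 (10.6 and 0.967) and SPC24 (22.2 and 3.56). The joined EHMT2,ZBTB12 locus, which holds a target of the inhibitor, was lower with BIX (22.7 and 10.8 in vector, 20.3 and 9.02 in KD), and so was SUV39H1 (17.5 and 9.74, 20.7 and 12.8).

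Immediate early genes had the highest list median, 2.41 in vector and 2.5 in KD, with 13 of 17 at least 2-fold higher in each. NF-kappaB and inflammatory genes were at 1.52 (10 of 16) and 1.48 (13 of 17), ATF4 targets at 0.77 (12 of 26) and 0.58 (11 of 26), BCL2 family genes at 0.50 and 0.56 and p53 targets at 0.57 and 0.47 (7 of 21 in each). DNA replication genes were lower (-0.56 and -0.53), as were mitosis genes (-0.28 and -0.33). The medians of these 7 lists lay outside 95% of random lists in both genotypes. Core autophagy genes were at 0.24 and 0.26 (percentiles 92.7 and 95.5), with MAP1LC3B at 49.8 FPKM in mock and 213 with BIX in vector, ATG12 at 9.76 and 30.4, and the receptor gene SQSTM1 at 64.2 and 170.5. Human interferon-stimulated genes had medians of -0.34 and -0.40, and 0 of 23 and 0 of 22 were 2-fold higher.

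Of 12364 genes in vector, 1314 were at least 2-fold apart (782 higher, 532 lower), and of 12401 in KD, 1448 (989 and 459). Centring the ratios on their median made these 642 and 689 in vector and 799 and 656 in KD, and a pseudocount of 0.1 made them 1023 and 1072 in vector, so the excess of higher genes in vector depended on both settings. For scale, 20, 20 and 31 genes were 2-fold apart between the 2 libraries of a group in the SETDB1 set. Among 9561 genes with FPKM of at least 5 in 1 of the values, 603 were higher and 276 lower in both genotypes, 0 were 2-fold apart in opposite directions, and the BIX ratios correlated at r = 0.921 over 12678 genes, which are not independent replicates.

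Between the ATG5 KD and vector cells, sterol synthesis genes differed most as a group. As ATG5 RNA showed no clear knockdown, a loss of ATG5 cannot be told apart from another difference between these cells. HMGCS1, an early enzyme of the mevalonate pathway, was at 14.0 FPKM in vector mock and 41.6 in KD mock, and at 33.8 and 161 with BIX. SQLE (21.2 and 55.6 in mock), FDFT1 (39.9 and 98.4), MSMO1 (20.2 and 46.8) and INSIG1 (3.38 and 8.84) were higher in KD too. The list median was 0.89 in mock (24 of 25 above 0, 9 of them 2-fold higher) and 0.82 in BIX (25 of 25 above 0, 3 of them 2-fold higher), above all 10000 random lists in both. Fatty acid synthesis genes were at 0.44 in mock, ribosomal protein genes at 0.28 and 0.40, and clustered protocadherins were lower (-0.44 in mock and -0.58 in BIX). Single genes higher in KD were TNNT2 (3.0 and 21.6 in mock) and NPPB (0.264 and 8.13), and SNAR-G1 was listed at 0 in both vector values and at 8.51 in KD mock. It is a short non-coding RNA gene that the name filter missed, so it is in these counts. CXCL14 (190.1 and 33.0), BPIFB4 (37.3 and 6.53), LAMA4 (5.01 and 1.10) and DYNC1I1 (11.9 and 3.24) were lower. In all, 118 of 12283 genes were 2-fold apart in mock (64 higher, 54 lower) and 225 of 12056 in BIX (170 and 55), and among the 9561 genes with FPKM of at least 5 in 1 of the values, 33 were higher and 22 lower in both. After centring, the mock split was 56 and 60, and the BIX split 151 and 66. At 1.5-fold the mock split was 230 and 251.

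**Figure D2:**
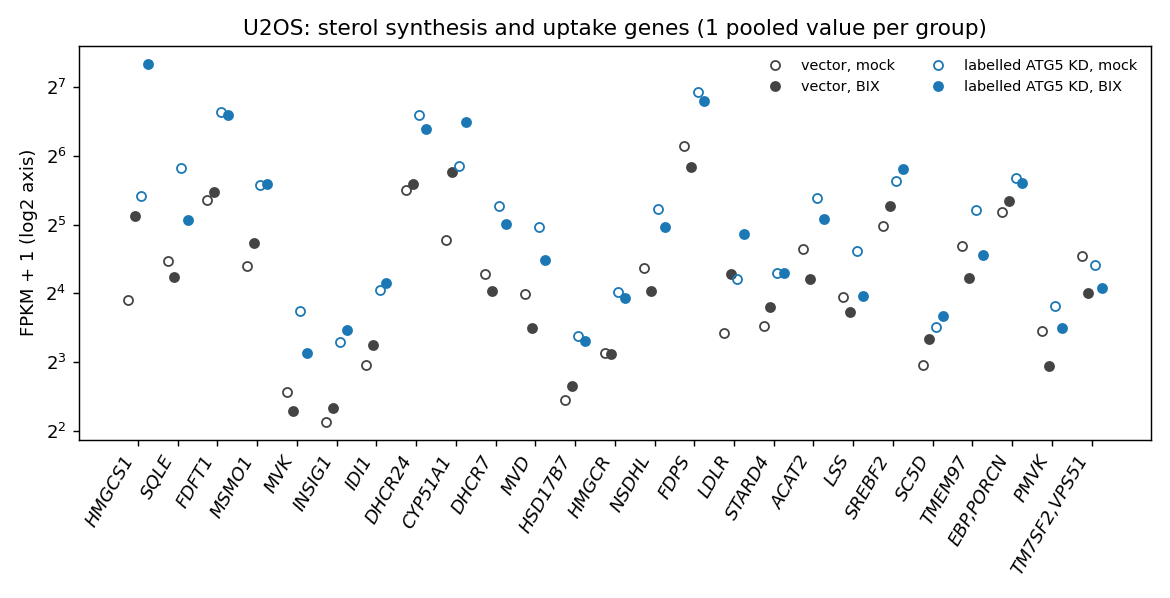
FPKM of 25 sterol synthesis and uptake genes in U2OS vector and ATG5 KD cells, mock and BIX (1 pooled value each).

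The BIX ratio itself was higher in KD than in vector by at least 1 (log2) for 62 of the 9561 genes and lower for 7. RRAD had a ratio of 1.15 in vector and 4.50 in KD, ARL14 1.91 and 4.12, and SYTL2 -1.97 and 0.46. CA11 (1.60 and -0.63), DNM1P46 (0.26 and -1.85), GPR1 (0.56 and -0.72) and ANO2 (1.69 and 0.55) had lower ratios in KD.

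In L929, BIX came with higher RNA of early response, NF-kappaB and interferon-stimulated genes and of single stress genes. Ppp1r15a was at 16.5 FPKM in mock and 324.9 with BIX in cGAS WT, and at 18.8 and 429 in cGAS KO. Gdf15, a stress cytokine gene, was at 62.7 and 1167 (KO 47.6 and 1006), Csrnp1 at 4.52 and 76.8 (KO 3.06 and 97.0), Ovgp1 at 11.8 and 153 (KO 6.59 and 181) and Rasl11a listed at 0 and at 8.59 (KO 0.0917 and 28.0). Lower in both were Islr (6.91 and 0.677 in cGAS WT), Gas1 (18.4 and 3.12), G0s2 (14.6 and 2.13), Trib2 (31.9 and 6.05) and Srebf1, a regulator of lipid synthesis (84.6 and 19.2). Ehmt2 was lower as well (67.3 and 31.1 in WT, 70.4 and 49.1 in KO).

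Immediate early genes were higher in both genotypes (list median 2.10 in WT and 2.09 in KO, 16 of 21 at least 2-fold higher in each), as were NF-kappaB genes (1.75 and 1.87, 15 of 19 and 12 of 19). ATF4 targets as a list were not higher (0.17 in WT, percentile 90.0, and -0.25 in KO, percentile 0.86). Gene by gene, the BIX ratio of NF-kappaB genes was lower in KO (median difference -0.19, percentile 1.41, 8 of 20 above 0), with 4 genes higher and 2 lower by at least 1. For immediate early genes the median difference was 0.17 (percentile 83.1). Mitosis genes were lower (-0.95 and -0.57), as were DNA replication genes (-0.73 and -0.48) and genes of the unfolded protein response of the endoplasmic reticulum (-0.92 and -0.41, 7 of 17 at least 2-fold lower in WT). Autophagy receptor genes were higher in WT (0.71, percentile 99.9). In KO their median of 0.67 lay within the range of random lists (percentile 97.2). Sqstm1 was higher in both (200 and 834 FPKM in WT, 237 and 616 in KO).

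Interferon-stimulated genes had a lower BIX ratio in cGAS KO than in cGAS WT. cGAS senses cytosolic DNA and signals to such genes. Ccl5 was listed at 0 in cGAS WT mock and at 215 FPKM with BIX, against 0.243 and 0.967 in cGAS KO. Cxcl10 was at 0.0957 and 181.7 in WT and at 0.188 and 2.82 in KO, Rsad2 at 0.0244 and 64.9 (KO 0.0485 and 0.218), Ifit1 at 0.179 and 67.5 (KO 0.0710 and 0.106) and Oasl1 at 0.544 and 97.7 (KO 1.17 and 7.61). Not all members differed: Irf9 was at 7.0 and 20.3 in WT and at 5.29 and 23.1 in KO. The list median was 1.46 in WT (25 of 37 at least 2-fold higher) and 0.75 in KO (11 of 27, percentile 99.9), so the list was higher in KO too. These medians cover different genes, since a gene at FPKM under 1 in both values of a genotype, Ifit1 in KO for one, is left out there. Over the 38 genes at FPKM 1 or more in any of the 4 libraries, the ratio was lower in KO by at least 1 in 18 (median difference -0.81, below all random lists). With BIX, 20 of 38 were at least 2-fold lower in KO (median -1.0). These differences between the genotypes were not tested. Among markers of blood and immune cells, Cd68 was at 41.2 and 80.3 FPKM in WT and at 5.11 and 29.6 in KO, and Cd79a at 0.537 and 17.1 in WT and at 0.227 and 21.5 in KO.

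**Figure D3:**
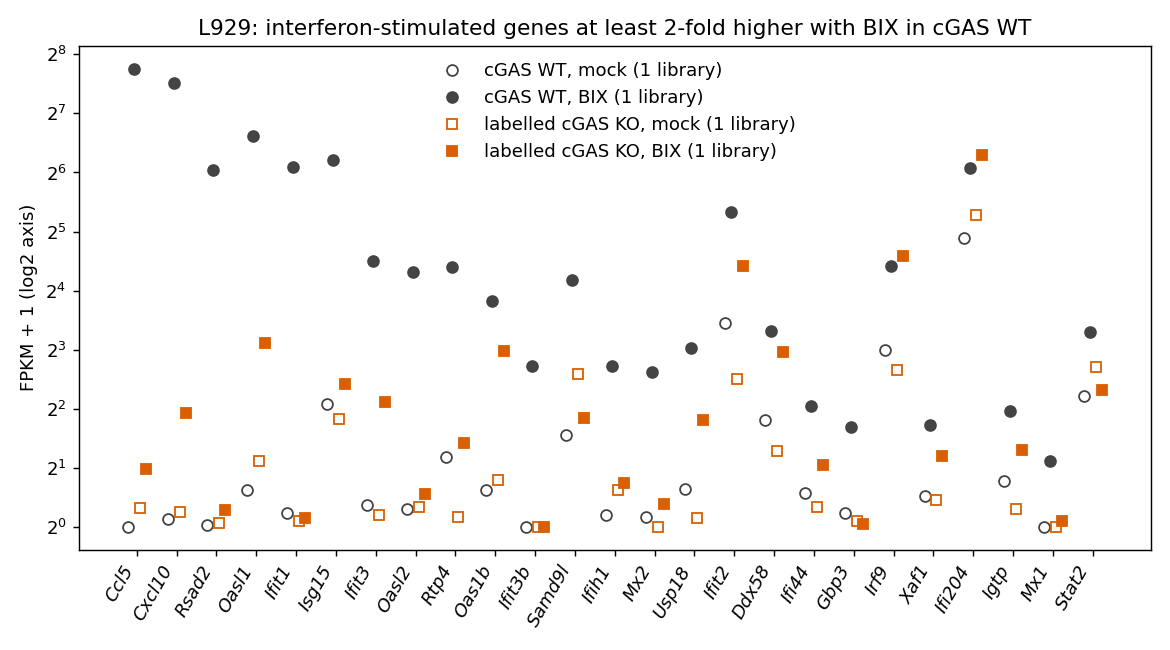
FPKM of 25 interferon-stimulated genes at least 2-fold higher with BIX in cGAS WT cells, in the 4 L929 libraries.

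Replication-dependent histone genes went the other way in these poly(A)-selected libraries. With BIX their median was 0.45 in WT (3 of 26 at least 2-fold higher) and 1.2 in KO (22 of 36), over different genes for the same reason. Over the 39 genes at FPKM 1 or more in any of the 4 libraries, 15 had a ratio higher in KO by at least 1 (median difference 0.78). Hist1h1e was at 0.439 and 0.976 FPKM in WT and at 0.143 and 10.4 in KO, and Hist1h4d at 2.33 and 4.31 in WT and at 0.441 and 11.9 in KO. Other genes with a higher ratio in KO were Tubb3 (listed at 0 in mock and at 0.382 with BIX in WT, 0.0564 and 9.85 in KO) and Gm20594 (3.40 and 3.73 in WT, listed at 0 and at 9.49 in KO), and Gm12238 was at 22.9 in WT mock and listed at 0 in the other 3 libraries.

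The 2 L929 lines also differed without BIX. Tgfbi was at 0.458 FPKM in cGAS WT mock and 86.5 in cGAS KO mock, Fmod at 0.0986 and 50.6, Agmo at 0.178 and 25.6 and the collagen gene Col3a1 at 1.10 and 43.5. Cd36, a fatty acid transporter gene, was at 148.3 and 1.49, and AI662270, H2-M10.1 and Ccl3 were at 45.2, 34.2 and 11.1 in WT and listed at 0 in KO. Extracellular matrix genes were higher in KO (median 0.48, 8 of 19 at least 2-fold). Genes of the unfolded protein response were lower (-0.99, 7 of 17 at least 2-fold), as were respiratory chain genes (-0.37) and replication-dependent histones (-0.54). With BIX, hypoxia and glycolysis genes were lower in KO (-1.03, 11 of 21 at least 2-fold).

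Of 10985 genes in cGAS WT, 1493 were at least 2-fold apart with BIX (817 higher, 676 lower), and of 11286 in cGAS KO, 2582 (1468 and 1114). KO against WT gave 854 of 10923 in mock (513 and 341) and 1318 of 11268 in BIX (725 and 593). After centring, the splits were 850 and 639 for BIX in WT, 1425 and 1148 in KO, 564 and 294 for KO against WT in mock, and 658 and 673 in BIX, so the direction with more genes turned in the last. It also turned for BIX in WT with FPKM of at least 5 (581 and 584) and at 1.5-fold (1809 and 2098), and for BIX in KO at 1.5-fold (2619 and 2716). Of 9303 genes with FPKM of at least 5 in 1 of the values, 202 were higher and 165 lower in KO in both treatments, 507 were higher and 390 lower with BIX in both genotypes and 1 was opposite. The BIX ratio was higher in KO by at least 1 for 238 of these and lower for 216, and the ratios correlated at r = 0.782 over 11616 genes, which are not independent replicates. The cGAS WT BIX library had 0.738 of the reads of cGAS KO BIX, so its low values were less precise.

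**Figure D4:**
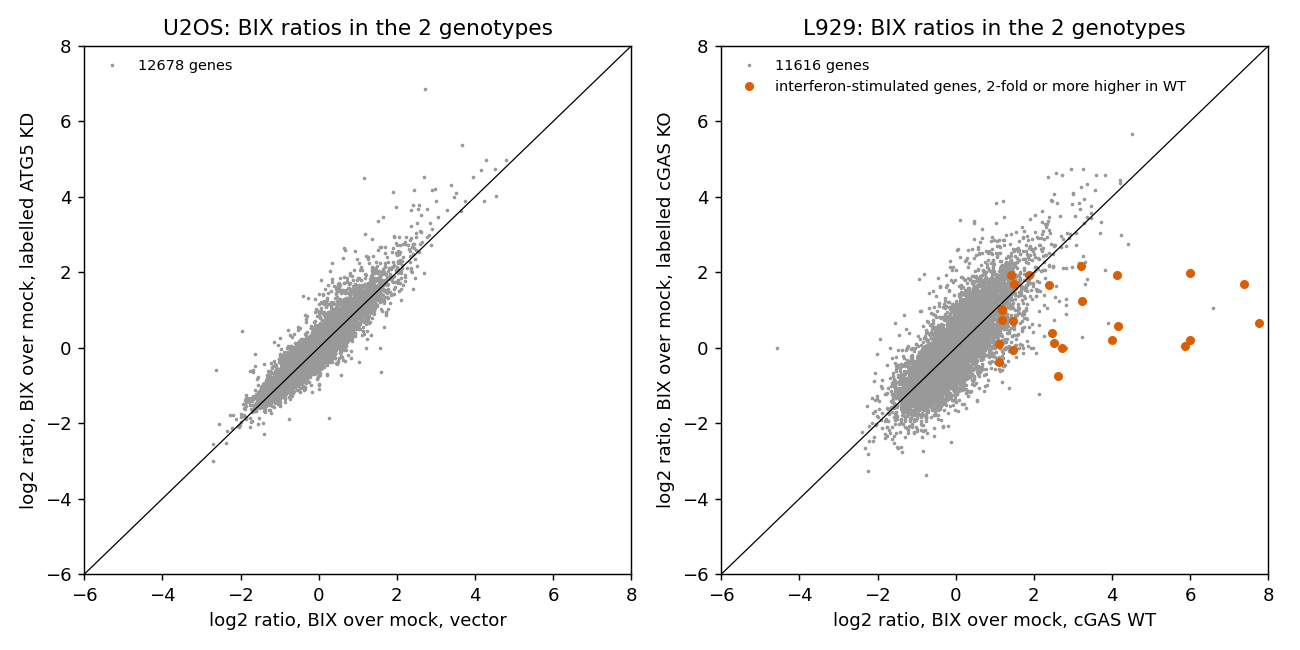
BIX log2 ratios in the 2 genotypes of U2OS (12678 genes) and L929 (11616 genes). Interferon-stimulated genes at least 2-fold higher in the control genotype are in orange, and the line marks equal ratios.

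Across the 4 backgrounds, the genes that rose most with BIX included stress and early response genes. PPP1R15A rose by 4.38 (SE 0.124, adjusted p = 0.000141), GDF15 by 4.17 (SE 0.111, adjusted p = 0.000141) and FOS by 4.04 (SE 0.371, adjusted p = 0.00631). EGR1 rose by 3.85 (SE 0.214, adjusted p = 0.0028), MAFF by 3.53 (SE 0.17, adjusted p = 0.0018) and DDIT3 by 3.35 (SE 0.632, adjusted p = 0.0187). These genes were chosen among those above 0 in 4 of 4. Among genes below 0 in 4 of 4, GAS1 fell by 1.93 (SE 0.283, adjusted p = 0.0108), and TRIB2 (-1.78), NEURL1B (-1.75), PSKH1 (-1.67), RGMA (-1.67) and TMEM37 (-1.64) followed. By list, immediate early genes rose in 13 of 21 (14 adjusted over the list alone), NF-kappaB genes in 12 of 20 (14 over the list alone; TNFAIP3 by 3.20) and lysosome genes in 10 of 31 (12). ATF4 targets rose in 6 of 26 and fell in 2 (7 and 3 over the list alone). Core autophagy genes rose in 7 of 26 and fell in 1 (7 and 1 over the list alone), among them MAP1LC3B by 1.57, GABARAPL1 by 1.49 and ATG101 by 1.33, and the receptor gene SQSTM1 rose by 1.57. DNA replication genes fell in 12 of 21 (15; MCM5 by 0.95) and mitosis genes in 7 of 20 (12; KIF20A by 1.34). Genes of p53 rose in 8 of 18 and fell in 2 (CDKN1A rose by 2.04). SREBF1 fell by 1.64 and SUV39H1 by 0.71.

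Of 13889 matched symbols, 10081 were tested and 2193 were called (1183 higher, 1010 lower). The same sign held in 4 of 4 backgrounds for 1181 of the higher and 1008 of the lower. The 2 backgrounds of a cell line are not independent of each other, so the p values are too small if the lines differ in their response. The count was 431 without U2OS vector, 301 without U2OS ATG5 KD, 1137 without cGAS WT and 1076 without cGAS KO. Centring each background on its median turned the split to 1113 higher and 1300 lower, so which direction held more genes depended on scaling.

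In U2OS, SETDB1 KO and BIX were compared over genes listed alike in both sets with FPKM of at least 1 in a vector value. This kept 199 of the 311 genes higher in the KOs and 83 of the 100 lower. Genes low in both vector values were thus left out. The 199 genes were higher with BIX about as often as independent lists would be, while the 83 were more often lower with BIX. The log2 ratios correlated at r = 0.097 over 10828 genes, which are not independent replicates. Of 199 genes higher in the KOs, 12 were 2-fold higher with BIX in vector cells (12.1 expected) and 5 were lower (9.0 expected). Of 83 genes lower in the KOs, 21 were lower with BIX (25.3% against 4.5% of all genes, 3.7 expected) and 8 were higher (5.1 expected). FOXS1, LBH, TNFAIP6, COL11A1, CAV1, SOCS1 and GJA1 were among the 21. The BIX side of this overlap was not tested.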

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

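All tests in this part were chosen only after the result was seen. Among genes with FPKM of at least 5 in 1 of the values, Myo1g was the 1 gene with opposite responses of at least 2-fold to BIX in the 2 genotypes of a line. It was at 0.0563 FPKM in cGAS WT mock and 3.66 with BIX (log2 ratio 2.14), and at 5.39 and 1.73 in cGAS KO (log2 ratio -1.23). The difference of -3.37 was not tested, as each value is 1 library, and no explanation was examined.

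Interferon-stimulated genes were higher with BIX in cGAS WT and less so in the library labelled cGAS KO. An exchange of the 2 BIX libraries is argued against, since 94.8% of 599 genes apart in mock kept their direction in BIX. Immune cells in the cGAS WT BIX library are argued against too: 0 of 13 blood and immune markers had an FPKM of at least 1 there and a BIX ratio higher by 1 or more than in KO, and the most abundant, Cd68, was at 80.3 FPKM with a larger ratio in KO. This count replaced an earlier median of the markers. A loss of cGAS cannot be told apart from another difference between the 2 lines, as 854 genes were at least 2-fold apart in mock, and Mb21d1 RNA was not lower in KO with BIX.

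Zinc finger genes rose in the SETDB1 KOs. Reads shared between such genes would not raise neighbours of other families. Yet 9 of 41 such neighbours of risen zinc finger genes were called higher against 11 of 327 beside uncalled ones (ratio 6.53, Fisher exact p = 7.53e-05). Shared reads thus do not account for these 9 neighbours. How far they raised the zinc finger genes themselves was not tested. At a gap of at least 10 kb the ratio was 4.75 (6 of 34 against 9 of 242, Fisher exact p = 0.00499). This argues against transcripts that run on over less than 10 kb, and cannot speak to longer ones. Neighbouring genes are not independent, so both p values are too small. Neighbours called higher included LINC00664, LINC00665, GPX3 and PIGG, and 294 of the 311 risen genes could be placed. A loss of silencing over whole regions is a hypothesis that stays open, and the chromatin samples were not analysed here.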

How the results depend on the processing

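Leaving out merged loci was chosen after the data were seen. Of 702 further fits of named SETDB1 KO genes, 44 no longer passed and 0 reversed. Of 887 of named 4-background genes, 188 no longer passed and 0 reversed. Of 4411 values of genes named by the fold limit, 12 moved and 0 reversed. Of 1384 list medians, 45 moved and 5 reversed, and of 161 values of the main counts and correlations, 38 moved. Pseudocounts of 0.1 and 0.5, scaling, kept short RNAs and left-out merged loci kept the 3 SETDB1 counts within 1.5 times their value. With FPKM of at least 5 they were 206 in the mean, 154 in KO1 and 150 in KO2, where fewer genes are tested. With no filter KO1 gave 180 and KO2 186. Leaving out 1 library gave 284 to 435 in the mean, 234 to 311 in KO1 and 171 to 363 in KO2, with a lone library assumed to vary like the other groups. The replicate numbers were taken as shared numbers only. Deviations of same-numbered libraries correlated at 0.364 (WT and KO1), 0.005 (WT and KO2) and 0.208 (KO1 and KO2). Yet the second principal component (19.8%) separated the numbers, and the steps of low FPKM values lined up within them. A batch by replicate number can therefore not be excluded, and the main counts leave it in the spread. A replicate block gave 511, 399 and 373 (157, 112 and 86 lower). With an estimated correlation, 0 lists passed. Lists past the test on the lower side ranged from 2 to 6 over the settings with the preset correlation.

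Counts of genes 2-fold apart moved with the limit, by construction. At 1.5-fold and 3-fold they were 3960 and 272 for BIX in vector, 4097 and 361 in ATG5 KD, 3907 and 347 in cGAS WT, and 5335 and 764 in cGAS KO. For KD against vector they were 481 and 16 in mock and 938 and 45 in BIX, and for cGAS KO against WT 2400 and 277 in mock and 3622 and 372 in BIX. A pseudocount of 0.1, which widens ratios of low values, gave 2095 for BIX in vector, 2316 in ATG5 KD, 264 for KD against vector in mock and 494 in BIX (345 at 0.5), and 2032 for cGAS KO against WT in BIX. With FPKM of at least 5, cGAS KO against WT in mock gave 555. The median of zinc finger genes with BIX reversed: -0.009 without a filter and -0.017 after centring in vector, and -0.008 and -0.077 in ATG5 KD. So did extracellular matrix genes in cGAS WT without a filter (0.039). Centring subtracts 0.079 from each ratio in vector and 0.096 in ATG5 KD. The zinc finger medians were positive but smaller than these values before centring, so their sign change with centring was arithmetic. The cause of the changes without a filter was not tested. In the single comparisons no replicates could be paired, and fits on replicate values were not run, as each group had 1 value. BIX and mock were paired by background in the test across the 4 backgrounds, and a fit within each line with genotype as a block was not run.

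Across the 4 backgrounds, no filter gave 1403 genes, a term for cell line 5614, and leaving out 1 background 301 to 1137. The cell line term takes the difference between the lines out of the spread, which leaves only that between the genotypes of a line. Its count therefore does not measure a response shared across lines. The causes of the other changes were not tested. The correlation of BIX with SETDB1 KO was 0.15 at FPKM of at least 5. Absolute depth is unknown, which limits what low values can show, most in the cGAS WT BIX library.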

Other observations

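The tests in this part were chosen only after the result was seen. Risen zinc finger genes in the SETDB1 KOs lay mostly on chromosome 19, which held 100 of the 146 that rose and 111 of the 315 that did not (Fisher exact p = 3.63e-11). ZFP30, ZNF578, LINC00664, LINC00665 and AURKC are on chromosome 19 too, while LINC01164 is on chromosome 10 and ACTL8 on chromosome 1. Neighbouring genes are not independent, so this p is too small.

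Replication-dependent histone genes were higher with BIX in the library labelled cGAS KO. Poly(A) selection favours polyadenylated forms of a transcript, so total histone mRNA may differ. A larger share of cells in S phase could be the reason for the higher values. For the higher values within cGAS KO, the DNA replication list argues against it, with a median BIX log2 ratio of -0.48. For the difference from cGAS WT the explanation stays open. The median difference of the BIX ratio of that list was 0.25 (KO minus WT, 21 of 23 above 0, percentile 96.2), within the range of random lists. The same list was higher in KO with BIX (median 0.66, 20 of 23 above 0, percentile 100) and in mock (0.40), and the BIX ratio of mitosis genes was higher in KO (0.36, 23 of 24 above 0, percentile 99.6). Another reason was not tested.

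The calls across the 4 BIX backgrounds were set against the other ways to give each background a sign. There are 8 such patterns, too few for a share under 0.05. The real pattern called 2193 genes and was the 1 pattern with that many, and the highest of the others called 0.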
